A study of Homo sapiens with 10 samples.

How the data were processed

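Nuclei of HEK293 cells were fractionated into a soluble nuclear extract (SNE, 3 samples) and a chromatin pellet extract (CPE, 3 samples), and chromatin pellets were also taken with DRB (2 samples) and with mock treatment (2 samples), per the labels. Libraries were stranded total RNA, per the labels' protocols. Reads were processed with TopHat2, an aligner, and Cuffdiff, which estimates and tests expression, on the human genome build hg19, per the submitters' processing notes. Versions, parameters, the transcript annotation and the scaling between libraries were not given in the sources used here.

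The gene table is a Cuffdiff difference table, per the file headers, with 241080 loci. It holds 1 FPKM value (fragments normalised to transcript length and library size) for SNE and 1 for CPE, which the authors computed over the replicates of each group. It also holds the authors' log2 ratio of CPE over SNE, their test statistic (an unscaled number, not used), and the p-value and q-value of their test. No per-sample values were in the table, so no SD or test across replicates could be computed, the depth of each library was unknown, and no interval for counting error was derived. The smallest p-value in the deposited table is 5e-05 and the smallest q-value 0.000706, shared by 13655 tested loci, so loci at that q cannot be ranked by it. The deposited log2 ratio was compared with the ratio of the 2 FPKM values at 178710 tested loci above 0 in both groups. It differed by over 0.01 at 637 loci, of which 65 were called and 2 had the opposite sign, and the deposited ratio was used.

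A locus was tested where its status was OK (192931 loci). Cuffdiff left 34611 loci untested for too few reads, 8580 as low data, 4921 as exceeding its data limit and 37 as failed. The loci above the limit lie in 31 regions, all of whose loci share that status, including regions of 34.0 Mb (3543 loci, 608 with a symbol) and 7.33 Mb (956 loci, 223 with a symbol). Values listed at 0 there are failed estimates and were not read as absence. The table gives the region of a bundle of loci in place of each locus's own coordinates. Start positions are printed here counted from 1, on hg19.

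A second deposited table lists 255974 isoforms. Pairs of FPKM values that occur once in each table (14208 pairs) stood under another gene identifier in 12307 cases (86.6%). Of its 567 regions with an isoform above the data limit, 398 had that status throughout. Its values were therefore taken not to belong to the identifiers beside them, and no isoform result is reported.

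A call was a status of OK and the authors' q of at most 0.05, in the direction of their log2 ratio. This rule gave the same calls as the table's own significance mark, with 0 differences. Loci were divided by whether they carry a symbol of their own (18271 tested, of which 1572 name several genes) or none (174660). The relation of direction to symbol was tested with Fisher's exact test, with a 95% interval of the odds ratio from its standard error on the log scale. The 17 gene lists were fixed before the data were examined. A list member was measured where it had a row with 1 symbol, a test and FPKM of at least 1 in either group. For each list, calls were counted by the authors' q and after Benjamini-Hochberg adjustment of the authors' p over the list alone. The median log2 ratio was placed among 10000 random lists of the same size, matched on 10 bins of mean FPKM. That percentile describes these libraries and is not a test across replicates. The random lists were not matched on gene length, with which the ratio rose among protein-coding genes, so length may contribute to a percentile.

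Genes were named by a rule fixed before the data were examined. From each list it took the 2 measured members of highest mean FPKM and the 2 called members with the largest absolute log2 ratio. Over all loci with 1 symbol and FPKM of at least 1 in both groups it took the 5 called loci with the largest and the 5 with the smallest ratio. Of loci without a symbol it took the 3 called loci of highest FPKM. Genes named after their values were seen are marked as such.

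Correlations with length used log10 length and log2((CPE + 0.1)/(SNE + 0.1)), a scale that understates the change of low genes, over loci with FPKM of at least 1 in either group. Gene type, gene length and longest transcript length came from GENCODE 29, matched by symbol or an older symbol. Its coordinates are on another build and were not used. A length was found for 10994 of 12630 measured loci with 1 symbol (87.0%). Neighbour analysis used the nearest region with a tested symbol locus within 100 kb and log2(FPKM + 0.1). Correlations and differences of medians were tested with 100000 random permutations, two-sided. The design fixed before the data were examined had foreseen coordinates for each locus, and the region was used in their place.

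Alternatives were a q of at most 0.01, an FPKM minimum, a minimum absolute log2 ratio of 1, centring of ratios on the median of loci with FPKM of at least 1 in both groups (a shift of -0.15), and equal sums without mitochondrial loci and the 100 most abundant (-0.19). For lengths and neighbours the alternatives were other filters, distances and pseudocounts. Centring and equal sums did not repeat the authors' test. They recounted the sign of the shifted ratio over the same called loci, and the authors' q still refers to the unshifted ratio. Centring on loci with a symbol (-1.33), regions without a symbol, single-locus regions, GENCODE lengths, merged loci and other summaries of neighbours were added after seeing the data. So were, for loci without a symbol, centring on all loci, equal sums and leaving out regions under 300 bases.

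The statistics were tested on simulated data with known answers. Of 40 simulated lists of 25 genes drawn at random from 12295 genes, 40 with a shift of 1 on the log2 scale and 22 with a shift of 0.5 lay at or above percentile 97.5, and 0 without a shift lay outside the central range. A simulated slope of 0.4 over 300 values was found in 40 of 40 cases and no slope in 1 of 40, and a shift of 0.6 in 39 of 40 and no shift in 4 of 40. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.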

Results

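RNA was measured in nuclei of HEK293 cells, an adherent line derived from human embryonic kidney, after the nuclei had been split into a soluble nuclear extract (SNE) and a chromatin pellet extract (CPE). Stranded total RNA libraries were labelled SNE in 3 samples and CPE in 3 samples, described as biological replicates of the fractionation. A further 2 chromatin samples were labelled with DRB, an inhibitor of transcription elongation by RNA polymerase II, and 2 were labelled as their mock treatment. The tables analysed here hold 1 FPKM value per gene for SNE and 1 for CPE, so no spread between replicates could be computed. Differences were therefore judged by the q value that the authors' Cuffdiff test assigned to each locus. Read depth per sample was unknown. The comparison addressed which RNAs remain with chromatin and which are released into the soluble part of the nucleus.

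The direction of enrichment differed between loci with and without a gene symbol. Of 18271 tested loci with a symbol, 7188 were higher in SNE, 335 were higher in CPE and 10748 were not called at q of at most 0.05. Of 174660 tested loci without a symbol, 16504 were higher in CPE, 1101 were higher in SNE and 157055 were not called. Together this gave 16839 loci higher in CPE and 8289 higher in SNE among 192931. Calls in CPE made up 93.7% of the calls at loci without a symbol and 4.45% of those at loci with one. The odds ratio of direction against symbol was 321.6 (95% interval 283.7 to 364.6, Fisher's exact test, two-sided, its p too small to be represented). Loci that share a region are not independent. How the loci without a symbol were defined was not given in the sources used here. If these same libraries defined them, the test is not independent of their selection. At FPKM of at least 1 in both groups, the median log2 ratio of CPE over SNE was -1.33 over 11388 loci with a symbol (interquartile range -1.89 to -0.60) and 1.45 over 13451 loci without one (0.17 to 2.29). The authors' scaling sets the zero of these ratios. Centring on the median of loci with a symbol, a shift of -1.33, was chosen after seeing the data. Of the called loci with a symbol, 1622 then had a ratio on the chromatin side and 5901 on the soluble side (21.6% on the chromatin side). The authors' q was not recomputed for centred ratios, so these are counts of sign and not calls.

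**Figure D1:**
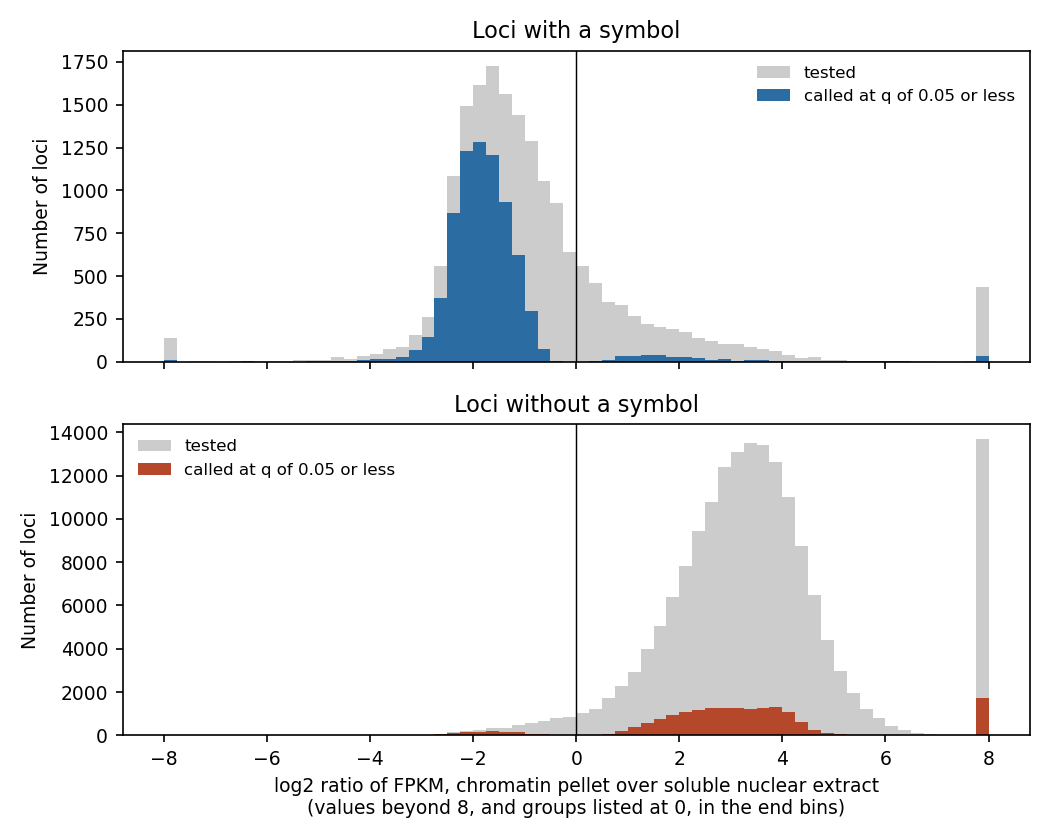
Number of tested loci (grey) and of loci called at q of at most 0.05 (coloured) by log2 ratio of FPKM, chromatin pellet over soluble extract, for loci with a symbol (upper panel) and without one (lower panel). Called loci with a symbol lie mostly below 0 (7188 against 335) and called loci without one mostly above 0 (16504 against 1101), with zero set by the authors' scaling.

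The small nucleolar RNAs SNORD13, SNORA31, SNORA34 and SNORA49 and the host transcript SNHG15 had the largest chromatin enrichment among called loci with 1 symbol and FPKM of at least 1 in both groups. In the authors' deposited table SNORD13, the nucleolar U13 RNA that acts in ribosomal RNA maturation, had an FPKM of 1059.5 in SNE and 70646 in CPE, a log2 ratio of 6.06 (q = 0.000706, the smallest q in the table). SNORA31, SNORA34 and SNORA49, nucleolar guide RNAs for pseudouridylation, had log2 ratios of 5.28, 5.07 and 5.00 in the authors' deposited table, each at the same q. The spliceosomal RNAs RNU4-2 and RNU5A-1 were 3.38-fold and 5.33-fold higher in CPE (q = 0.000706 for each in the authors' deposited table). By GENCODE type, 19 small nuclear and 4 small nucleolar RNA loci with 1 symbol were higher in CPE, 0 of either type were higher in SNE, and 194 and 69 were not called. These counts are incomplete, since a type was found for 61.9% of such loci higher in CPE and 93.8% of those higher in SNE. Of 7 measured members of the list of nuclear ribonucleoprotein RNAs, 6 were higher in CPE and 1 was not called, and 7 were higher in CPE when adjusted over the list alone. The list median of 1.92 lay at percentile 99.97 of 10000 random lists matched on mean expression. A further 7 members, among them RN7SK and RNU1-1, could not be tested because their regions exceeded Cuffdiff's data limit. Another 14 of the 28 members with a row of their own were not tested for other reasons or were under the FPKM minimum. The libraries' treatment of RNAs this short was not given in the sources used here, so their FPKM ranks transcripts less reliably than it does longer ones.

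Among long non-coding RNAs, NEAT1, MALAT1 and FTX were higher in the chromatin pellet. NEAT1, the scaffold of paraspeckles, had an FPKM of 4.11 in SNE and 44.6 in CPE in the authors' deposited table (10.8-fold, q = 0.000706; region on hg19 chromosome 11, 65190245 to 65216687). MALAT1, a nuclear speckle RNA, was 2.73-fold higher in CPE and FTX, which lies in the X inactivation centre, was 4.45-fold higher (q = 0.000706 for both, from the authors' deposited table). DLEU2 had FPKM values of 23.5 and 84.6 in the authors' deposited table and was not called (q = 0.119). HOTAIR, HOTAIRM1 and HOXA11-AS, transcribed from HOX clusters and named here after their values were seen, were higher in SNE, with log2 ratios of -1.33, -1.21 and -1.75 in the authors' deposited table. Centring on loci with a symbol removes a shift of -1.33, about the ratio of HOTAIR itself. HOTAIR and HOTAIRM1 then turned only slightly to the chromatin side, without a test of the centred ratio, so no chromatin enrichment is read from them. The 9 measured members of the chromatin lncRNA list thus divided into 3 higher in CPE, 3 higher in SNE and 3 not called, and into 4 and 3 called members when adjusted over the list alone. Their median log2 ratio of 0.64 lay at percentile 99.95 of matched random lists. After centring, the ratios of the called members lay on the chromatin side for 5 and on the soluble side for 1, a count of signs and not of calls.

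The list of processed and cytoplasmic non-coding RNAs divided between the fractions. SNHG15, SNHG1 and SNHG7, which carry small nucleolar RNAs in their introns, were higher in CPE by 11.4-fold (q = 0.000706), 7.38-fold (q = 0.0103) and 6.34-fold (q = 0.000706) in the authors' deposited table. SNHG5 and SNHG8, named after their values were seen, were 7.18-fold and 4.86-fold higher in CPE in the authors' deposited table. In the same list RPPH1, the RNA of ribonuclease P, and the transcripts DANCR, LINC00152, LINC00657 and ZFAS1, also named afterwards, were higher in SNE, with log2 ratios between -2.03 and -1.19 in the authors' deposited table. DANCR and ZFAS1 are also hosts of small nucleolar RNAs. The hosts GAS5, SNHG6 and SNHG16, named afterwards, were not called, with log2 ratios of 2.74, 0.27 and -1.24 in the authors' deposited table (q = 0.427, 0.844 and 0.133). Of 16 measured members 5 were higher in CPE, 5 were higher in SNE and 6 were not called, with 5 and 8 called when adjusted over the list alone. The list median of -0.72 (percentile 99.77 of random lists) became 0.62 after centring on loci with a symbol. The ratio of ZFAS1 then changed sides, which left 6 called members on the chromatin side and 4 on the soluble side, without a new test. Reads of an intronic small RNA and of its host could not be separated at these loci.

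Messenger RNAs for the translation and energy machinery were higher in the soluble extract. RPS19, RPL37A and RPS15, components of the cytosolic ribosome, were 6.33-fold, 5.88-fold and 6.27-fold higher in SNE (q = 0.000706 for each in the authors' deposited table). Of 43 measured ribosomal protein genes 39 were higher in SNE, 1 was higher in CPE and 3 were not called, and adjusted over the list alone 40 and 1 were called. The exception was RPS27, named after its value was seen, with FPKM values of 8.91 in SNE and 20.1 in CPE in the authors' deposited table. Ribosomal protein genes have many processed pseudogenes, so read assignment among copies is uncertain. Of 39 measured nuclear-encoded respiratory chain genes 38 were higher in SNE and 1 was not called, and 39 were called in SNE when adjusted over the list alone. COX6B1, a subunit of cytochrome c oxidase, had an FPKM of 1909 in SNE and 361.2 in CPE, and the ATP synthase subunits ATP5B, ATP5D and ATP5G1 were 4.23-fold, 6.60-fold and 6.01-fold higher in SNE in the authors' deposited table (q = 0.000706 for each). Median log2 ratios of the ribosomal and respiratory lists were -2.27 and -2.22, both below all 10000 random lists matched on mean FPKM. Gene length was not matched, and protein-coding genes of up to 12.1 kb had a median of -1.92. The lengths of list members were not compared, so short length may contribute. With loci that name several genes counted as well, 7 ribosomal protein loci were higher in CPE and 45 were higher in SNE.

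Replication-dependent histone transcripts, which lack introns and poly(A) tails, were also higher in the soluble extract. HIST1H1E and HIST1H2BJ had FPKM values of 1832 and 1690 in SNE against 379.6 and 313.6 in CPE in the authors' deposited table. HIST2H3D and HIST1H2BO were 6.49-fold and 5.92-fold higher in SNE in the authors' deposited table (q = 0.000706 for all of these histone genes). Of 23 measured members 19 were higher in SNE, 4 were not called and 20 were called in SNE when adjusted over the list alone. Their median log2 ratio was -2.33, below all 10000 random lists, and it stayed below 0 after centring on loci with a symbol (-0.99). The random lists were not matched on gene length, so short length may contribute here too. Histone genes of a family are near-identical in sequence, which makes the value of each member uncertain.

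Genes of the secretory pathway, the proteasome, the immediate early response and the p53 response were mostly higher in SNE, with medians inside the range of random lists of like expression. CANX, an endoplasmic reticulum chaperone, P4HB, a disulfide isomerase, SEC61B, a translocon subunit, and the amino acid transporter SLC7A5 were 3.90-fold, 4.25-fold, 5.43-fold and 5.64-fold higher in SNE in the authors' deposited table (q = 0.000706 for each). Of 44 measured secretory and membrane protein genes 35 were higher in SNE and 9 were not called (38 adjusted over the list alone; median -1.82, percentile 6.91 of random lists). The proteasome subunits PSMB6, PSMB1, PSMB3 and PSMA3 were 5.86-fold, 5.20-fold, 4.82-fold and 3.75-fold higher in SNE in the authors' deposited table (q = 0.000706 for each). Of 27 measured proteasome genes 25 were higher in SNE and 2 were not called (26 adjusted over the list alone; median -1.90, percentile 16.2). KLF10 and JUND were 7.09-fold and 6.71-fold higher in SNE, and ID2 and MCL1 were 2.76-fold and 2.43-fold higher, at q = 0.000706 in the authors' deposited table, and MCL1 changed sides after centring on loci with a symbol. Of 30 measured immediate early genes 24 were higher in SNE and 6 were not called (25 adjusted over the list alone; median -1.60, percentile 10.55). CDKN1A, the p53-induced cell cycle inhibitor, and the apoptosis genes BAX and PMAIP1 were 5.54-fold, 5.22-fold and 3.08-fold higher in SNE at q = 0.000706 in the authors' deposited table. Of 18 measured p53 targets 12 were higher in SNE and 6 were not called (16 adjusted over the list alone; median -1.57, percentile 23.55). Centring on loci with a symbol changed the sign of the ratio at 7 of the 35 secretory, 4 of the 25 proteasome, 6 of the 24 immediate early and 1 of the 12 p53 genes called in SNE. The authors' q was not recomputed, so these genes, MCL1 among them, are not calls in CPE. All 4 medians lay below those of their random lists (-1.61, -1.73, -1.32 and -1.37 in the order above), and in simulation a shift of 0.5 was found in only 22 of 40 lists, so a smaller difference from other genes is not excluded.

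Transcripts of splicing regulators, KRAB zinc fingers and very long genes were less depleted from chromatin than other genes of like expression. That comparison did not match gene length, with which the ratio also rose. Of 26 measured splicing regulators and genes with detained introns, 3 were higher in CPE, 7 were higher in SNE and 16 were not called (5 and 9 adjusted over the list alone). ANKRD36 was 4.04-fold higher in CPE in the authors' deposited table (q = 0.000706), and its near-identical paralogs leave that value uncertain. CCNL1, a cyclin of splicing kinases, and NKTR, both named after their values were seen, were 2.52-fold (q = 0.000706) and 2.21-fold (q = 0.0299) higher in CPE in the authors' deposited table. SRSF3, a serine/arginine-rich splicing factor, was 4.62-fold higher in SNE in the authors' deposited table (q = 0.000706). HNRNPH1 and SRSF5, the most abundant members, were not called, with log2 ratios of -0.88 and -0.21 in the authors' deposited table (q = 0.223 and q = 0.489). Of 53 measured KRAB zinc finger genes, which encode transcriptional repressors, 18 were higher in SNE and 35 were not called (20 adjusted over the list alone). ZNF74 and ZNF213 were 5.88-fold and 4.88-fold higher in SNE (q = 0.000706), and ZNF227 and ZNF226 had log2 ratios of -0.09 and -0.43 without a call (q = 0.672 and q = 0.175), all in the authors' deposited table. Of 25 measured very long protein-coding genes, only CDH4 and CNTNAP2 were called, 3.60-fold (q = 0.000706) and 3.64-fold (q = 0.00616) higher in SNE in the authors' deposited table, and 23 were not called (the same 2 called in SNE adjusted over the list alone). EXOC4 and TCF4, the most abundant of them, had log2 ratios of 0.18 and -0.13 in the authors' deposited table (q = 0.615 and q = 0.844). The medians of the splicing, zinc finger and very long gene lists were -0.17, -0.52 and -0.12, at percentiles 100, 100 and 99.97 of random lists. These medians turned positive after centring on loci with a symbol, to 1.16, 0.82 and 1.21. Among members already called, the centred ratio lay on the chromatin side for 7 splicing regulators and 12 zinc fingers. It lay on the soluble side for 3 and 6. These are counts of sign and not calls, since no centred ratio was tested and uncalled members could not enter.

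Factors of the DRB target pathway, P-TEFb and its partners in elongation, were higher in the soluble extract or not called. NELFB, a subunit of the negative elongation factor, and MEPCE, the capping enzyme of 7SK RNA, were 6.85-fold and 4.35-fold higher in SNE in the authors' deposited table (q = 0.000706 for both). PAF1 was 2.59-fold higher in SNE (q = 0.0352), and CCNH, at FPKM values of 89.9 and 51.3, was not called (q = 0.188), in the authors' deposited table. Of 27 measured members 14 were higher in SNE and 13 were not called, with 21 higher in SNE when adjusted over the list alone. The median of -1.06, at percentile 91.9 of random lists, became 0.28 after centring on loci with a symbol. Of the 14 called members, 4 then had a ratio on the chromatin side and 10 on the soluble side, with no new test.

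**Figure D2:**
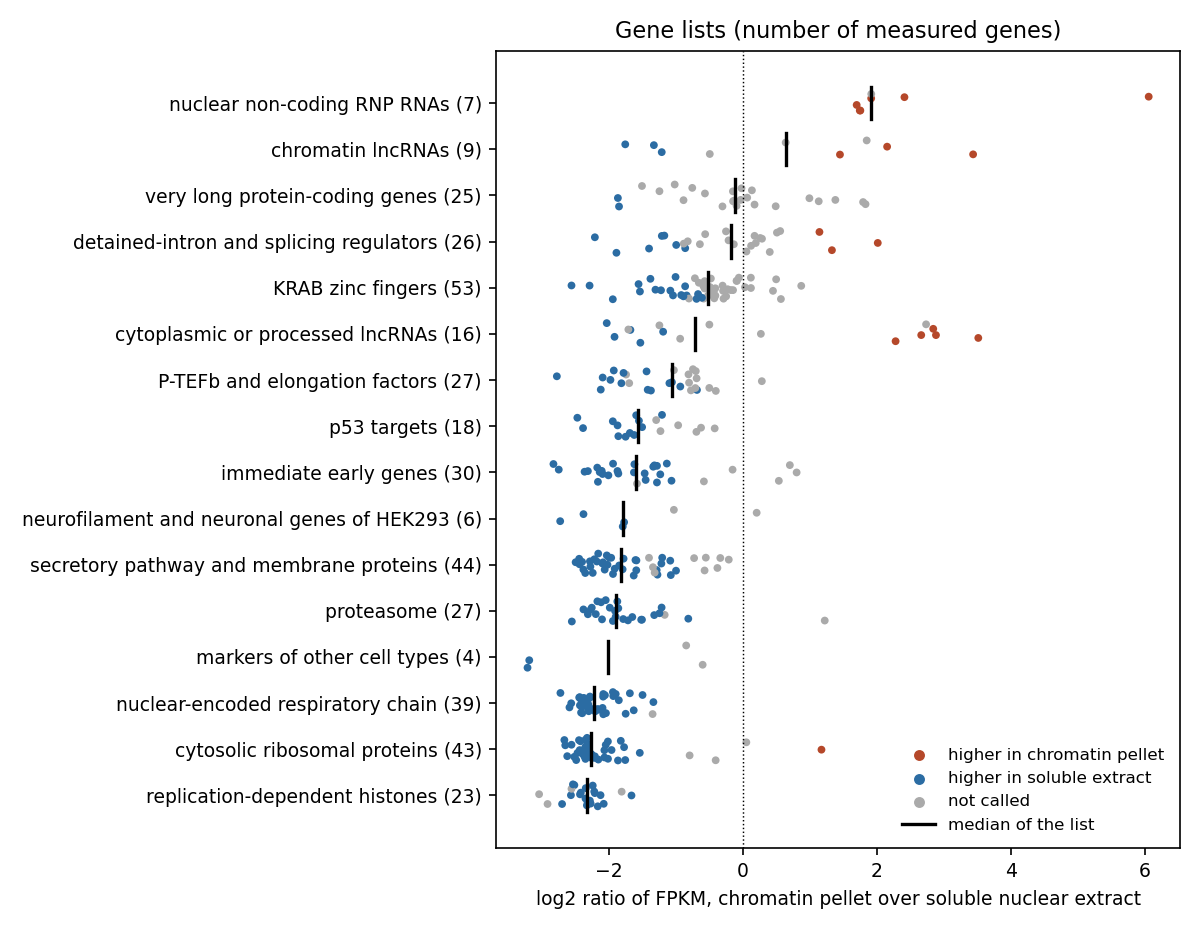
Log2 ratio of FPKM, chromatin pellet over soluble extract, for each measured gene (points, coloured by the authors' call) in the 16 gene lists with a measured member, with the median of each list as a black bar. Nuclear ribonucleoprotein RNAs have the highest median (1.92) and replication-dependent histones the lowest (-2.33). Medians of the processed lncRNA, splicing, zinc finger, very long gene and P-TEFb lists turn positive after centring on loci with a symbol.

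Over all called loci with 1 symbol and FPKM of at least 1 in both groups, the lowest ratios belonged to AL162853.1, C4orf3, GAS1, FOXD1 and KCTD5. AL162853.1, a locus of 75 bases, was 13.5-fold higher in SNE (q = 0.0439) and C4orf3 was 13.2-fold higher (q = 0.000706) in the authors' deposited table. GAS1, a membrane protein linked to growth arrest, the transcription factor FOXD1 and KCTD5 were 11.3-fold, 10.8-fold and 10.7-fold higher in SNE in the authors' deposited table (q = 0.000706, 0.000706 and 0.00517).

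Markers of other cell types were mostly at low FPKM, and 25 of the 29 with a row of their own were not tested or under the FPKM minimum. APOA2, an apolipoprotein, and HBA1, a globin gene with a near-identical copy, had FPKM values of only 1.14 and 1.79 in SNE and were 9.27-fold (q = 0.000706) and 9.11-fold (q = 0.00134) higher there than in CPE in the authors' deposited table. MBP and COL1A1 were not called, at log2 ratios of -0.84 and -0.60 in the authors' deposited table (q = 0.187 and q = 0.407). Of the 4 measured markers, 2 were higher in SNE (3 adjusted over the list alone; median -2.02, percentile 11.2 of random lists). Of 6 measured members of the list of neuronal genes, some of which HEK293 cells are known to express, 4 were higher in SNE and 2 were not called (4 adjusted over the list alone; median -1.78, percentile 20.55). Of the 17 members with a row of their own, 11 were not tested or under the FPKM minimum. UCHL1 and VIM were 3.46-fold and 3.41-fold higher in SNE, and STMN3 and SYP were 6.61-fold and 5.20-fold higher, at q values of at most 0.00665 in the authors' deposited table. Mitochondrially encoded genes, a gauge of cytoplasmic carry-over, could not be measured because all 4 of their loci were above Cuffdiff's data limit.

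Loci without a symbol that were higher at chromatin were mostly weakly expressed. Their median FPKM was 1.43 in CPE and 0.170 in SNE, and 1721 of them were listed at 0 in SNE. With FPKM of at least 1 required in either group, 10753 were higher in CPE and 1098 in SNE. With that minimum required in both groups, 2183 of 3104 calls (70.3%) were in CPE, against 146 of 6106 calls (2.39%) at loci with a symbol. In regions that hold no locus with a symbol, an alternative chosen after seeing the data, 4927 were higher in CPE and 134 in SNE. The 3 called loci of highest FPKM were short and higher in SNE. CLOC_043902 (in a region of 410 bases on hg19 chromosome 13, 21668457 to 21668866), CLOC_126721 (229 bases on chromosome 4, 55842310 to 55842538) and CLOC_060268 (66 bases on chromosome 16, 31173332 to 31173397) had log2 ratios of -2.43, -2.94 and -2.58 in the authors' deposited table (q = 0.000706 for each). FPKM divides by a very small length at such loci, which inflates it.

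Genes near chromatin-enriched loci without a symbol were more highly expressed than genes near soluble-enriched ones. The nearest region with a symbol within 100 kb had a median SNE FPKM of 13.97 for 15745 loci higher in CPE and of 7.08 for 1056 loci higher in SNE, taking the highest gene of the region. The difference of medians of log2(FPKM + 0.1) was 0.97 (permutation test, two-sided, p = 1e-05, the smallest p that 100000 resamples can give). Loci that shared a region with the gene were included, and they made up 11195 and 840 of the 2 sets. Regions were longer for the loci higher in CPE, with a median of 59827 bases against 19854, and loci of 1 region are not independent. A longer region can hold more genes from which the highest is taken. With the median of the region's genes instead, chosen after seeing the data, the SNE FPKM medians were 9.02 and 5.19, a difference of 0.79 on the log2 scale.

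Long genes were relatively more abundant at chromatin than short genes. Among 9423 protein-coding genes matched by symbol to GENCODE 29, the median log2 ratio was -1.92 in the shortest length bin (up to 12.1 kb) and -0.87 in the longest (from 111.0 kb). Calls in SNE covered 74.6% of genes in the shortest bin, 63.7% in the middle bin and 26.9% in the longest. Across these genes Spearman's rho between log10 gene length and log2((CPE + 0.1)/(SNE + 0.1)) was 0.41 and Pearson's r was 0.40 (permutation test, two-sided, p = 1e-05 for both and also after Benjamini-Hochberg adjustment over the 7 settings, the smallest possible). Gene length replaced region length after the data had been seen, since the table gives the region of a bundle of loci and not the coordinates of each. The planned correlation with region length, over 105910 loci, gave rho of 0.41 and r of 0.33 (p = 1e-05), and it reversed to rho of -0.25 and r of -0.21 in 3797 regions with 1 locus (p = 1e-05). Over 10994 genes of all types the coefficients differed in sign (rho 0.22, r -0.22). Genes are not independent replicates, and these correlations are across genes.

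**Figure D3:**
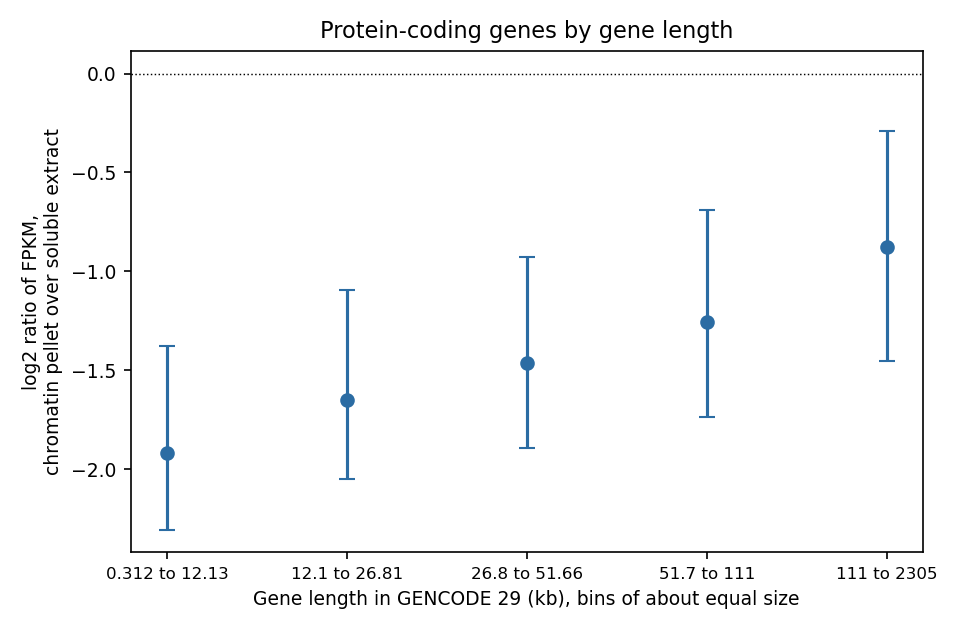
Median (point) and interquartile range (bars) of the log2 ratio of FPKM, chromatin pellet over soluble extract, in 5 bins of protein-coding genes by gene length in kb. The median rises from -1.92 in the shortest bin to -0.87 in the longest, relative to the authors' scaling.

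The 2 samples labelled DRB and the 2 labelled mock were not analysed here. The effect of DRB on chromatin RNA, its overlap with chromatin enrichment and the difference between mock and untreated chromatin samples are therefore not given.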

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

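All alternatives that centre on loci with a symbol, count merged loci, use regions with 1 locus or regions without a symbol, take gene lengths or use other summaries of neighbours were chosen after seeing the data. So were, for loci without a symbol, centring on all loci, equal sums and leaving out regions under 300 bases. No paired analysis was possible because the tables hold 1 value per group. For the same reason the planned settings without each replicate and with limma, and counts over other splits of the samples, were not run, and depth limits could not be assessed. Planned settings for DRB and mock were not run because the tables hold no values for those samples. Those for isoforms were not run because the isoform values were taken not to belong to the identifiers beside them. Among values under alternatives, 160 kept their direction and threshold side or stayed within 1.5 times the main count, 20 counts moved further and 1 correlation reversed. Centring on all loci and equal sums could not change any count, because no called ratio lay from -0.25 to 0. Their values are among the 160 and say nothing about stability. An FPKM minimum of 1 in either group lowered the loci higher in CPE from 16839 to 10983, and those without a symbol from 16504 to 10753, since fewer loci are counted. Only regions without a symbol gave 4927 and 134 loci without a symbol, from 16504 and 1101, for the same reason. Centring on loci with a symbol raised the called loci with a symbol on the chromatin side from 335 to 1622, by sign alone and without a new test. It gave CPE counts of 5 for chromatin lncRNAs (SNE 1), 7 for secretory genes, 7 for splicing regulators (SNE 3), 6 for immediate early genes, 1 for p53 targets, 4 for P-TEFb factors, 4 for the proteasome and 12 for KRAB zinc fingers (SNE 6), because a called ratio between -1.33 and 0 changes sign. Counting merged loci gave 1 nuclear ribonucleoprotein locus in SNE, 7 ribosomal protein loci in CPE and 5 splicing regulator loci in CPE, as more loci are counted. At FPKM of at least 0.1, 1 marker of other cell types was higher in CPE. The correlation of ratio with region length, 0.41, reversed to -0.25 in regions with 1 locus, and the cause was not tested. Its other alternatives stayed between 0.22 and 0.41 (permutation p = 1e-05 for each, the smallest possible). The neighbour difference of 0.97 ranged from 0.79 to 1.64 over 7 alternatives.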

Other observations

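Tests of the authors' scaling, of low values in SNE, of transfer RNA genes and of the distance to histone genes, and the description of merged loci and gene types, were chosen only after the results they bear on had been seen; the other tests of explanations were written down before their result was seen.

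Merged loci that name a small nucleolar or Cajal body RNA were called higher in CPE more often than other merged loci. Of 67 such loci 18 (26.9%) were higher in CPE, against 31 of 1505 others (2.06%; odds ratio 17.5, Fisher's exact test, two-sided, p = 8.62e-14). Their median log2 ratios were 0.35 and -1.18. The merged locus of EIF4A1, a translation initiation helicase, with CD68, SENP3, SNORA48, SNORA67 and SNORD10 had an FPKM of 7736 in SNE and 157951 in CPE in the authors' deposited table. The merged locus of EIF4A2 with SNORA4, SNORA63, SNORA81 and SNORD2 had 3450 and 108633 in the authors' deposited table. Such values belong to the locus as a whole and not to the messenger RNA.

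Among the 286 loci with 1 symbol that were higher in CPE, 177 (61.9%) matched a GENCODE 29 gene, too few to test types. The matched ones comprised 77 protein-coding genes, 22 lincRNAs, 19 small nuclear RNAs, 15 processed pseudogenes, 10 antisense RNAs, 4 small nucleolar RNAs and 30 loci of other types. Of the 6523 higher in SNE, 6120 matched, and 5620 of these were protein-coding. XIST, the RNA that coats the inactive X chromosome, RN7SK, RN7SL1, RMRP and RNU1-1 have no test because their regions exceed the data limit, and nothing is read from their values.

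Loci without a symbol lay on the chromatin side (93.7% of their calls) and loci with one on the soluble side. Whether the way loci without a symbol were defined contributes to this contrast was not tested. The authors' scaling cannot produce this contrast alone, since 1 factor moves both kinds alike and at matched mean FPKM the median log2 ratio still differed by 2.44 (bootstrap 95% interval 2.37 to 2.501). Low values in SNE account for part of the excess at most, since the share of calls in CPE was lower but still 70.3% (exact 95% interval 68.7 to 71.9) at FPKM of at least 1 in both groups. Unspliced RNA of an annotated gene in the same region cannot cover the loci in regions without a symbol, where at FPKM of at least 1 in either group 1338 of 3279 loci (40.8%) were called higher in CPE, a share 3.84 times (95% interval 3.67 to 4.02) that of 9415 of 88583 (10.6%) in regions with one. Calls in SNE were also more frequent there (132 of the 3279 against 966 of the 88583), so the 3.84 reflects more calls in both directions and not a stronger lean to chromatin. Unspliced RNA of a gene in another region nearby was not tested as a source. Without an FPKM minimum, 4550 loci higher in CPE lay within 100 kb of a region with a tested symbol locus that they did not share. For the 9415 loci higher in CPE in regions with a symbol, unspliced RNA of a gene in the region remains open and may contribute. Over the 2347 loci higher in CPE at that minimum that share a region with exactly 1 gene, their CPE FPKM followed that of the gene (Spearman's rho 0.51, permutation p = 1e-05, the smallest possible). Shared regulation of neighbours would also give this. Loci in regions with several genes were not tested in this way.

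A group of short loci without a symbol on hg19 chromosome 6, between 26 and 29 Mb, was higher in CPE. In that window 17 of 98 tested loci in regions of at most 500 bases had FPKM of at least 50 in CPE and a call there (median log2 ratio 1.20, median region length 246.0 bases), against 4 of 4838 outside all windows. Of the called loci without a symbol higher in CPE, the 3 of highest CPE FPKM, CLOC_064197 on chromosome 17 and CLOC_148060 and CLOC_148113 on chromosome 6, had 1751, 1463 and 1184 in the authors' deposited table. Those on chromosome 6 lie in regions of 194 and 126 bases. CLOC_064197 lies in a region of 57696 bases that holds 16 loci, so it is not one of the short loci. Reads of histone genes stay open. None of the 17 loci (0%, exact 95% upper bound 19.5%) shared a region with a histone symbol, but neither did any of the other 81, so the limit on region length fixes that outcome and it decides nothing. The 17 loci lay a median of 254.8 kb from the nearest region with a histone symbol and the other 81 lay 215.2 kb from it, a difference in median log10 distance of 0.0734 (permutation test, two-sided, p = 0.446) that does not decide it either. The 29 histone loci in the window had a median log2 ratio of -2.27. Transfer RNA genes, which cluster there, are a candidate source: in 6 other windows known for them, 4 of 35 short loci met the same criteria (odds ratio 155.9, Fisher's exact test p = 1.53e-07), and without the chromosome 16 window, whose locus had been seen before the windows were listed, 3 of 30 did (odds ratio 134.3, p = 7.27e-06). Transfer RNA annotation on hg19 was not used here, so no locus was identified.

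The ratio rose with length of protein-coding genes (rho 0.41), and the technical explanations tested were settled only in part. Expression level is argued against by rho between 0.34 and 0.51 in each of 5 bins of mean FPKM. Overlap of loci in shared regions is argued against only for 88 genes in regions with 1 locus. Over these rho was 0.50 (permutation p = 1e-05, the smallest possible). They are few of the 9423 genes, so the part of overlap at the other genes was not decided. The length of the spliced transcript went with part of the rise, since rho fell to a partial rho of 0.24 given the longest transcript. The longest transcript may differ from those expressed here. The partial rho therefore cannot show whether spliced length accounts for all of the rise. As a hypothesis that was not tested here, a larger share of the RNA of long genes may be nascent or unspliced and so held at chromatin, which could be examined with intron and exon reads. Differences in RNA stability or export between long and short genes were not tested.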
